A study of Homo sapiens with 32 samples.

How the data were processed

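Total RNA of 16 established human colorectal cancer cell lines was hybridised to CodeLink UniSet Human arrays, 2 arrays per line from separate experiments, 32 arrays in all. Per the labels, cells were grown with serum in a medium that varied by line (RPMI 1640, L-15, D-MEM F-12 or McCoy's 5A), RNA was extracted with Qiagen RNeasy, and biotin-labelled cRNA was made from 2 µg of total RNA with the CodeLink Expression Assay Kit. The scanner and its software are not given in the sources used here.

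The array files deposited by the authors hold a raw intensity, a normalized intensity and a quality flag for each spot. The raw intensity was already background-subtracted as deposited, since negative control spots lie near 0 and some values are negative. The normalized intensity as deposited equals the raw intensity divided by the array's median over gene probes, with a largest difference of 0.00106 from that quotient, and the deposited series table repeats the normalized intensity with 0 cells differing. Its medians were 0.940 to 0.976 over all spots and 1 over gene probes. Of 20500 spots per array, 20012 were gene probes, 300 negative controls and 188 other controls. The flags G, L, M, C, I and S were read as good, not above background, masked, contaminated, irregular and saturated; the meaning of a further flag, P, is not given in the sources used here, and its spots were kept. Masked spots, 234 to 340 per array, carry no value.

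Raw intensities of gene and negative control probes were quantile-normalized over the 32 arrays, floored at the 95th percentile of the negative controls (21.2 intensity units, log2 4.40) and put on the log2 scale. The floor held 11.2% of the values. The normexp correction planned with offset 50 needs spot and background signals, which the files do not give, and the floor was chosen after the files were seen. A probe was tested when it lay above background on both arrays of at least 1 line, which 15965 probes did and 4047 did not. The number of arrays, with median raw intensities of 32.2 to 249, limits the precision.

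One mean per line was fitted with limma 3.58.1 in R 4.3.3 (jsonlite 2.0.0 for the labels), with 16 residual and 4.22 prior degrees of freedom. Line differences were tested with the moderated F test, each line against the equally weighted mean of the other 15, and 5 pairs of lines of a shared recorded origin directly. A probe was called at a Benjamini-Hochberg adjusted p below 0.05 within the contrast and at least 2-fold. Leaving out 1 array leaves a line with 1 array, which is then assumed to vary like the others. The 2 experiments of a line were treated as replicates, and whether they were separate cultures is not given in the sources used here.

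Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 352 tests of lines and over the 110 tests of pairs. The 22 lists held 673 genes, 457 of them measured here by a probe that passed the filter. They covered enterocyte differentiation, goblet and mucin, Paneth, Wnt target and intestinal stem cell, neuroendocrine, mesenchymal, epithelial junction and keratin, cancer-testis, interferon response, antigen presentation, DNA mismatch repair, proliferation, p53 target, xenobiotic metabolism and transport, cholesterol synthesis, hypoxia and glycolysis, NF-kappaB and chemokine, EGFR ligand and MAPK output and HOX genes, and markers of fibroblasts, leukocytes and endothelium as other cell types. Similarity of lines was the Pearson correlation across probes of line means centred per probe, and the mean over pairs of a shared origin minus that over other pairs was tested by 100000 permutations of the line names, two-sided, with seed 1. Origins came from cell line records: SW480 and SW620 from 1 patient, CX-1 tied to HT-29, and HCT-15, HCT-8 and CloneA tied to DLD-1.

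Probes were named from the array's annotation table through current gene symbols. Of the gene probes 15678 had 1 symbol (15634 through a gene identifier, 44 by the table's own name), 790 had several and 3544 none. Among the tested probes 12765 had 1 symbol, for 11120 genes. The genes named in the text follow a rule: a probe with 1 symbol, the probe with the highest mean for each gene; the 10 genes with the largest range among those past the F test; the 4 largest increases and 2 largest decreases of each line; the 10 and 10 largest of SW620 against SW480, 6 and 6 of CX-1 against HT-29, and 4 and 4 of the other pairs; from each called list members in order of size, up to 4; and a panel of 16 genes. Symbols that are only clone or open reading frame names were skipped. For the panel, 7 of the 16 genes had no probe named to them and were not analysed here.

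The tests, thresholds, lists, groups and naming rule were set before the data were examined, the floor excepted. Calls, camera, the F test and the similarity test were tried on simulated data built on the spread of these arrays. At each fold 100 of 15965 probes were changed, all over 4-fold above the floor. Recovery at 4-fold was 98% in COLO320 against the rest and 94% in SW620 against SW480. At 2-fold 74% and 37% passed the adjusted p, with 6 and 9 false calls. The 2-fold rule left 44% and 29%, with 0 and 5.

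Other settings tried were a floor at 1, median scaling, cyclic loess, the deposited series table's values, no filter, a filter on all 32 arrays, the experiment as a block, the array series as a block, array quality weights, contaminated and irregular spots set missing, no fold threshold, treat at 1.5-fold, 1 probe per gene, an estimated correlation, Spearman correlation, the 1000 probes of largest SD, families without CloneA or HCT-8, and leaving out each array. Control spots were left out of the comparisons. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.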

Results

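Messenger RNA was measured in 16 human colorectal cancer cell lines with single-colour CodeLink oligonucleotide arrays, and the experiment was carried out 2 times for each line, which gave 32 arrays. The lines were CloneA, COLO205, COLO320, CX-1, DLD-1, HCT-8, HCT-15, HCT116, HT-29, LoVo, LS180, SW48, SW480, SW620, SW948 and T84, each with n = 2 arrays. Each array read 20012 gene probes as fluorescence intensity. The median raw intensity of an array ranged from 32.2 (HCT-15, first array) to 249 (SW948, second array), with a median of 55.1 over the arrays. Between 9492 probes (47.4%, HCT-15, first array) and 14253 probes (71.2%, HCT116, first array) lay above background, and the median was 13331 (66.6%). The first SW620 array had 10523 probes above background (52.6%). The number of arrays, 2 per line, limits the precision of every difference given here. The p-values and standard errors rest on the spread between the 2 arrays of a line, pooled over all lines for each probe, which may be technical. They do not reflect a line's own spread. The SD of the difference between the 2 arrays was 0.80 in SW620 and 0.32 in DLD-1, so errors are understated for SW620.

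The labels state no aim beyond profiling the lines. The comparisons therefore ask in which genes the lines differed, how each differed from the mean of the others, and how lines of a shared recorded origin differed. Differences are given on the log2 scale with the standard error of the fit. Where a gene was above background on only a minority of the arrays of the dimmer group, or saturated in the brighter, the difference is a bound, written "at least N-fold". It sets the bright group's mean against the dim group's mean, in which each array not above background counts with the higher of the lowest signal among its probes above background and the dim probe's own signal. All 96 differences named for single lines had both arrays of the line on the reported side of the mean of the other lines, and the largest adjusted p among them was 2.75e-06 (SPINK1 in HCT-8). Other genes named as members of gene lists had adjusted p below the threshold of 0.05 unless stated.

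Each of the 32 arrays correlated most highly with the other array of its own line, with r across probes from 0.597 (SW620) to 0.895 (COLO320). The highest correlation with an array of another line was 0.511, between DLD-1 and HCT-15. Probes are not independent replicates, so these correlations carry no p. The 2 arrays of SW620 differed at least 2-fold on 16.4% of probes, against 0.909% (HCT116) to 6.66% (HCT-15) in the other lines.

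Each of the 10 genes named for a large range over the lines was above background on neither array of at least 1 line, so the ranges are lower bounds and their order is not determined. The secreted phospholipase PLA2G2A was above background in 8 lines and on neither array of 7, with its highest mean in COLO205 (at least log2 14.95), where its spots were saturated (adjusted p = 2.32e-08). The calcium-binding protein S100P was highest in HT-29 (14.43, adjusted p = 2.44e-10), and its relative S100A14 was highest in LoVo (14.15, adjusted p = 1.29e-13). Both were lowest in COLO320, as were the glutathione transferase MGST1 and the steroid-reducing enzyme AKR1C3. The secretory-pathway disulfide isomerase AGR2 was highest in LS180 (13.95, adjusted p = 1.68e-16), with 11 lines above background and 4 not. The tetraspanin TSPAN8 was highest in LoVo (13.85) and not above background in HCT116. The phospholipid acyltransferase PLAAT3 was highest in HT-29 (13.53) and lowest in CloneA. The trypsin inhibitor SPINK1 was highest in CX-1 (13.45) and the serine protease KLK7 in SW48 (13.28), each on neither array above background in 6 lines.

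Of 15965 probes tested, 14156 (88.7%) differed between lines by limma's F test (adjusted p below 0.05), and 1809 did not. The range of line means was at least 2-fold for 13365 of the differing probes, at least 4-fold for 7027 and at least 16-fold for 1245. The median SD was 0.28 within a line and 0.53 between line means.

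Of a fixed panel of 16 tumour and intestinal markers, 9 had a probe here. The intestinal transcription factor CDX2 was highest in COLO320 (log2 11.34 ± 0.40, SD, n = 2) and CloneA (9.15), and COLO320 exceeded COLO205 at least 103-fold (F test, adjusted p = 9.03e-13). The epithelial adhesion molecule EPCAM ranged at least 293-fold, from 14.04 ± 0.10 in SW948, where it was saturated, to 5.84 in COLO320 (adjusted p = 4.12e-16). The p53-regulated cell-cycle inhibitor CDKN1A ranged 129-fold, from 12.43 ± 0.79 in LS180 and 12.40 in HCT116 to 5.42 ± 0.06 in COLO320 (adjusted p = 3.21e-08). The growth factor EREG was highest in HCT116 (12.34 ± 0.38), at least 172-fold above COLO320 (adjusted p = 6.07e-06). The stem-cell receptor LGR5 was above background in 4 lines and highest in T84 (7.57 ± 0.07), at least 7.96-fold above SW480 (adjusted p = 5.49e-08). The goblet-cell mucin MUC2 was highest in LS180 (7.31 ± 0.26) and LoVo (5.81), with a range of at least 6.67-fold (adjusted p = 4.01e-07). The neuroendocrine granule protein CHGA was above background in all lines and varied by 1.49 (adjusted p = 3.35e-05). For the p53 regulator MDM2, above background on both arrays of 1 line and on neither of 8, no difference was detectable at this signal (range 0.79, adjusted p = 0.102), and CDX1 was above background on both arrays of no line.

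**Figure D1:**
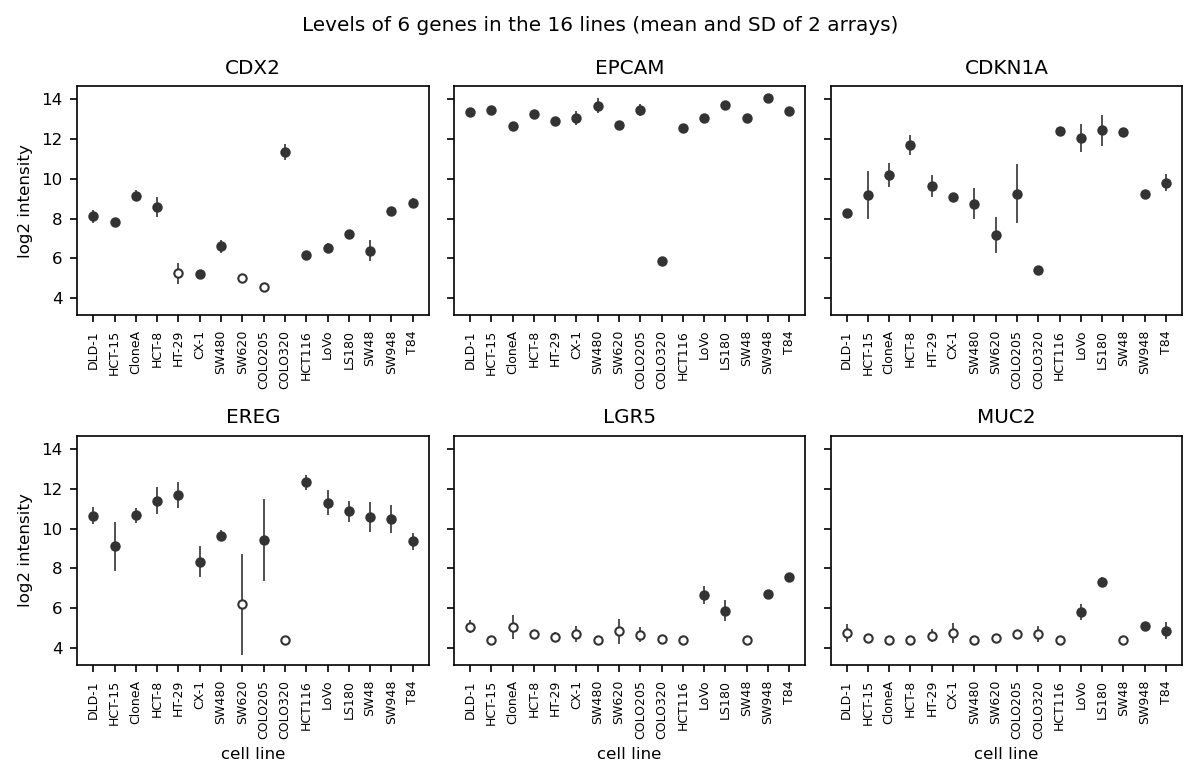
Log2 signal of 6 panel genes in the 16 lines, as mean and SD of the 2 arrays, with open symbols where the gene was not above background on both arrays. EPCAM and CDKN1A were lowest in COLO320, the line in which CDX2 was highest.

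Lines that cell line records tie to each other were compared with unrelated lines. DLD-1 and HCT-15 had the highest correlation of line means across probes (r = 0.569), followed by CX-1 and HT-29 (0.446) and by CloneA and DLD-1 (0.336). SW480 and SW620, derived from a primary tumour and a lymph node metastasis of 1 patient, correlated at 0.143. HCT-8 did not resemble the lines it is tied to (-0.146 with DLD-1), except CloneA (0.201), and was closest to SW948 (0.271). The most similar unrelated lines were LoVo and LS180 (0.324), and the least similar were DLD-1 and SW480 (-0.413). The mean r was 0.213 over 8 pairs of shared origin and -0.0853 over all other pairs, a difference of 0.298 (two-sided permutation test over line names, p = 4.0e-05). Probes are not independent replicates, so the test permuted lines.

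**Figure D2:**
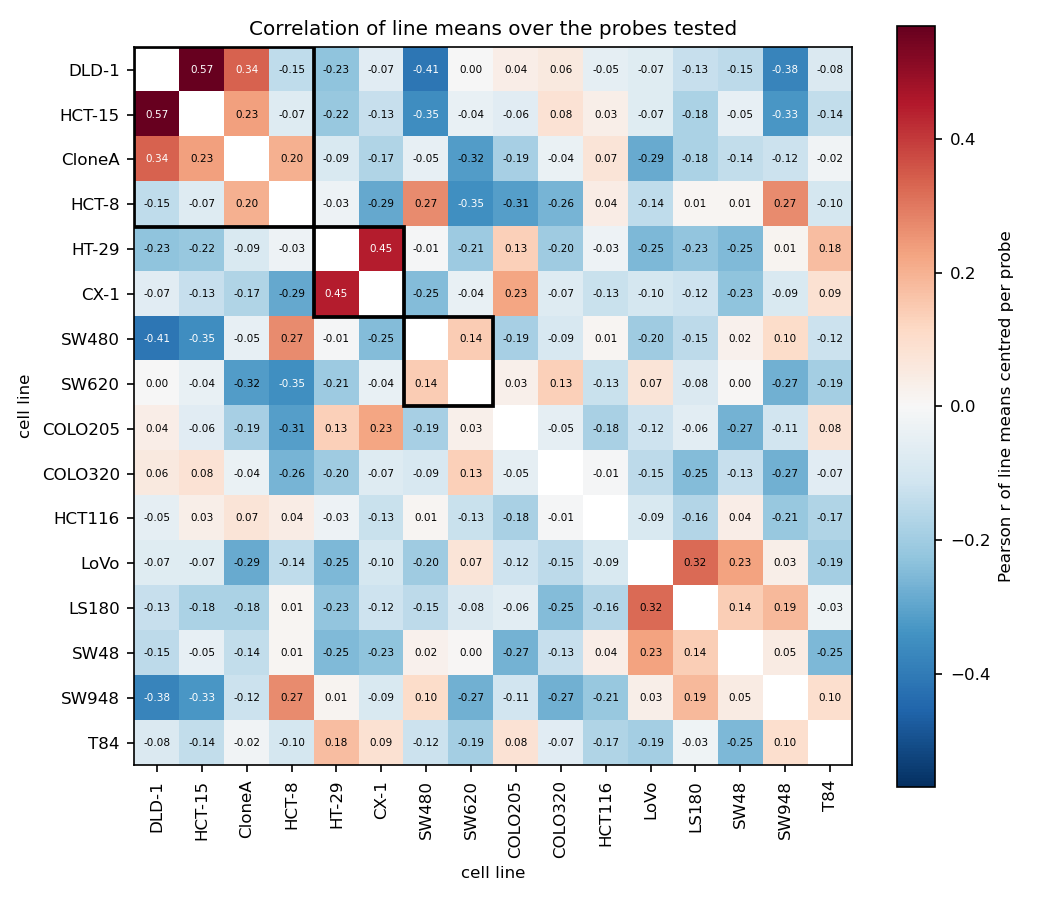
Pearson correlation across probes of the centred line means, for each pair of the 16 lines, with boxes around lines of a shared recorded origin. DLD-1 and HCT-15 are the closest pair (0.569), and HCT-8 lies at -0.146 with DLD-1.

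Each line was then set against the mean of the other 15. The called probes, at adjusted p below 0.05 and at least 2-fold, ranged from 1397 (HCT-15) to 2933 (SW480) of 15965. The median of all probes was shifted by -0.12 in HCT-8, -0.11 in SW480 and -0.11 in SW948, and with median scaling by -0.15 in HT-29, -0.12 in HCT116 and -0.11 in T84. The 22 gene lists were tested with camera at a preset correlation. With an estimated correlation 3 of the 56 list calls over lines and 1 of the 9 over pairs held, and for 62 of the 65 called tests this alternative gave the highest adjusted p, the strictest filter aside. No called list had a median, mean and test of different sign.

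**Figure D3:**
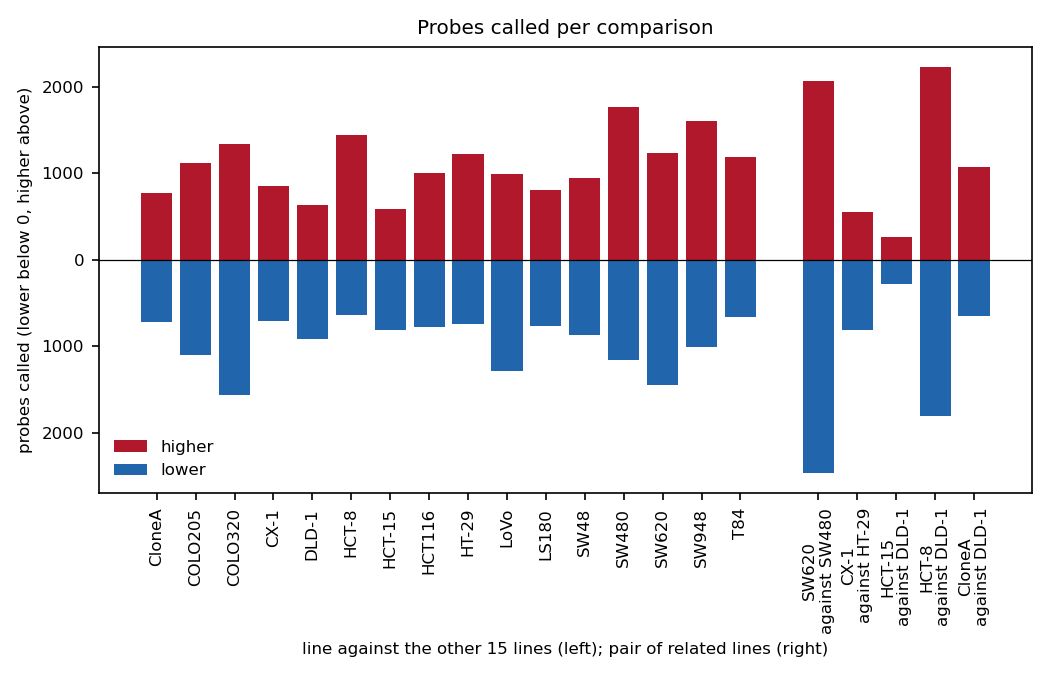
Number of probes called higher (above 0) and lower (below 0) in each line against the other 15 and in each pair of lines, at adjusted p below 0.05 and at least 2-fold. SW480 has the most among the lines (2933) and SW620 against SW480 the most among the pairs (4536).

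In CloneA the imprinted noncoding RNA H19 was higher by 7.09 ± 0.18 (SE, n = 2), although its second probe was not called (0.505). REG1A, a secreted regenerating protein above background on 4 of the 30 other arrays, was at least 43.4-fold higher, and the potassium channel subunit KCNJ8 was higher by 5.05 ± 0.21. ODAM, a secreted protein first known from tooth enamel, was at least 17.6-fold higher. PLAAT3 was at least 96.5-fold lower, and the glutamine synthetase GLUL was lower (-5.10 ± 0.16). Of the called probes 767 were higher and 723 lower. Antigen presentation genes were lower (median -0.59, adjusted p = 0.000346, 7 of 19 members lower and 1 higher), among them the immunoproteasome subunits PSMB9 (at least 14.1-fold) and PSMB8 (at least 12.7-fold), and adjusted p = 0.393 with an estimated correlation. That median was -0.36 without the second CloneA array. Interferon-response genes were lower (median -0.63, adjusted p = 0.0118, 9 of 33 members, 11 adjusted over the list alone), led by IFI35 (at least 14.3-fold) and IFI27 (-3.43 ± 0.42), with adjusted p = 0.727 with an estimated correlation. Enterocyte genes were lower (median -0.22, adjusted p = 0.0274, 6 of 24 members lower and CDX2 higher by 2.08), including the lectin LGALS4 (-3.65 ± 0.23) and the peptidase DPP4 (at least 7.57-fold), with adjusted p = 0.361 with an estimated correlation, and the call ended without the second CloneA array (median -0.15). Cancer-testis genes, normally active in the germ line, were lower (median -0.18, adjusted p = 0.0118) with 1 of 17 members called, MAGEA12 (at least 3.19-fold), and adjusted p = 0.101 with an estimated correlation, and with the floor at 1 that call ended (median -0.52, adjusted p = 0.138).

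In COLO205 PLA2G2A was at least 420-fold higher (n = 2), with saturated spots. The cornified-envelope precursor SPRR1A (at least 97.2-fold), the lymphocyte kinase LCK (at least 42.2-fold) and the secreted gut protein PRAP1 (5.40 ± 0.25, SE) were also higher. The ubiquitin ligase UBE2O was at least 34.6-fold lower, and NPDC1, a regulator of neural proliferation above background on 1 of the 2 arrays, was lower (-5.29 ± 0.29). In all 1120 probes were higher and 1106 lower. Genes of epithelial junctions were higher (median 0.74, adjusted p = 0.000346, 8 of 31 members), led by LAD1 (2.28 ± 0.18) and the epithelial factor ELF3 (2.08 ± 0.28), with adjusted p = 0.164 with an estimated correlation and a median of 0.49 without the second COLO205 array. Antigen presentation genes were higher (median 0.94, adjusted p = 0.000346, 9 of 19 members), led by PSMB8 (3.01 ± 0.27) and the protease CTSS (2.40 ± 0.22), with adjusted p = 0.392 with an estimated correlation. Xenobiotic metabolism genes were higher (median 0.29, adjusted p = 0.0429, 11 of 30 members higher and 3 lower), with adjusted p = 0.323 with an estimated correlation. The gut glutathione peroxidase GPX2 was up by 4.99 ± 0.34 and the drug pump ABCB1 at least 11.2-fold lower. Enterocyte genes were higher by the same test (median 0.25, adjusted p = 0.0429, 6 of 24 members), with LGALS4 up by 3.98 ± 0.23 but CDX2 at least 6.55-fold lower (second probe -1.75), and adjusted p = 0.381 with an estimated correlation. Without the first COLO205 array these last calls ended, for enterocyte genes at a median of 0.18 and for xenobiotic genes at 0.29 (0.45, still called, without the second), and the enterocyte call ended with median scaling (0.21) and cyclic loess (0.23).

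In COLO320 the neuronal and neuroendocrine deubiquitinase UCHL1 was at least 248-fold higher and the histamine-forming enzyme HDC at least 87.0-fold higher (n = 2), and neither was above background in any other line. The matrix protein THBS4 (at least 112.5-fold) and the transcription factor TCF4 (at least 93.1-fold, second probe 1.93) were higher as well. S100A14 was at least 187-fold and MGST1 at least 179-fold lower (second MGST1 probe -2.54). Probes called numbered 1333 higher and 1563 lower. Lower as a group were epithelial junction genes (median -1.38, adjusted p = 2.98e-12, 18 of 31 members lower and 1 higher), and this call held at adjusted p = 0.0420 with an estimated correlation. They included EPCAM (-7.38 ± 0.14, SE), KRT19 (at least 63.2-fold, although its second probe differed by 0.138), the trafficking protein RAB25 (at least 56.7-fold) and the protease inhibitor SPINT2 (at least 40.3-fold). Xenobiotic genes were lower (median -1.06, adjusted p = 0.000977, 15 of 30 members lower and 3 higher), led by AKR1C3 (at least 33.0-fold) and GPX2 (at least 13.3-fold), with adjusted p = 0.101 with an estimated correlation. EGFR ligand and MAPK output genes were lower (median -1.07, adjusted p = 0.00188, 10 of 23 members lower and 2 higher, 11 and 2 adjusted over the list alone), led by EREG (at least 37.4-fold) and IER3 (-4.95 ± 0.37), with adjusted p = 0.377 with an estimated correlation. Antigen presentation genes were lower (median -0.60, adjusted p = 0.00834, 7 of 19 members), led by PSMB9 (at least 9.90-fold) and PSMB8 (at least 8.97-fold), with adjusted p = 0.541 with an estimated correlation. Cancer-testis genes were higher (median 0.47, adjusted p = 0.00762, 4 of 17 members), led by MAGEA12 (at least 40.5-fold) and PRAME (at least 11.2-fold), with adjusted p = 0.101 with an estimated correlation. Without the filter on dim probes that call ended (median 0.08, adjusted p = 0.0528), and with cyclic loess the median was 0.27.

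In CX-1 the cancer-testis gene PAGE5 was at least 83.8-fold higher (n = 2) and was above background on 3 of the 30 other arrays. The gastric annexin ANXA10 (at least 77.3-fold), the trypsin inhibitor SPINK1 (5.63 ± 0.48, SE) and the retinol carrier RBP4 (at least 40.9-fold) were higher, while the tubulin TUBB6 was at least 31.4-fold and the neuropeptide GAL at least 20.8-fold lower. The counts were 849 higher and 706 lower. Cancer-testis genes were higher (median 0.05, adjusted p = 0.000815, 6 of 17 members, MAGEA12 at least 41.8-fold), a call that held at adjusted p = 0.0428 with an estimated correlation. It did not hold with only probes above background on all 32 arrays, where the median turned to -0.85, and the median was 0.16 without either CX-1 array. Goblet-cell genes were higher (median 0.29, adjusted p = 0.00172, 7 of 19 members, 8 adjusted over the list alone), led by the disulfide isomerases AGR3 (5.08 ± 0.30) and AGR2 (3.64 ± 0.26), with adjusted p = 0.128 with an estimated correlation. Epithelial junction genes were higher (median 0.46, adjusted p = 0.000196, 6 of 31 members), among them SPINT2 (1.36 ± 0.18) and the plaque protein JUP (1.34 ± 0.21), with adjusted p = 0.164 with an estimated correlation. RAB25 was called too (1.51 ± 0.20), but at 0.65 not among the 27 arrays that leave out SW480 and SW620, which lack it. Interferon-response genes were lower (median -0.67, adjusted p = 0.00106, 11 of 33 members, 12 adjusted over the list alone), led by IFITM1 (at least 12.8-fold) and IFITM3 (-3.87 ± 0.39), with adjusted p = 0.627 with an estimated correlation.

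In DLD-1 the slow-muscle troponin TNNC1 was higher by 4.85 ± 0.32 (SE, n = 2), the glutathione transferase GSTM3 by 4.07 ± 0.18 (second probe 2.59), the calmodulin regulator PCP4 by 4.05 ± 0.42 and the chemokine CCL26 at least 12.7-fold. The epidermal secreted protein DMKN was at least 19.7-fold and GPX2 at least 17.3-fold lower. There were 636 probes higher and 920 lower, and 460 and 1058 with cyclic loess. Genes of epithelial junctions were higher (median 0.52, adjusted p = 0.0238, with 4 of 31 members higher and 4 lower), among them PERP (1.57 ± 0.18) and CRB3 (1.49 ± 0.17) against DSC2 (-2.00 ± 0.23, second probe -0.203). That call had adjusted p = 0.389 with an estimated correlation and ended without the second DLD-1 array (median 0.45).

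In HCT-8 the aldo-keto reductase AKR1B10 was higher by 5.80 ± 0.58 (SE, n = 2), the interferon-induced IFI27 by 4.17 ± 0.42, the alarmin cytokine IL33 by 3.98 ± 0.29 and the protocadherin FAT1 by 3.79 ± 0.23. The RNA-binding protein RBMS1 was at least 18.6-fold (second probe -2.08) and SPINK1 at least 13.6-fold lower. Of the probes 1436 were higher and 639 lower, and 1696 and 437 with cyclic loess. Cancer-testis genes were lower (median -0.47, adjusted p = 0.00422, 3 of 17 members), among them MAGEA12 (at least 2.68-fold) and MAGEB2 (-1.39 ± 0.24), with adjusted p = 0.10 with an estimated correlation. The call of the third, DDX43 (-1.37), ended with the array series as a block (-0.94) and without the first HCT-8 array (-0.79).

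In HCT-15 KCNJ8 was higher by 4.61 ± 0.21 (SE, n = 2), the Ras-binding protein RASIP1 by 4.19 ± 0.38, the protease inhibitor CST6 by 4.09 ± 0.32 and GSTM3 by 3.99 ± 0.18 (second probe 2.17). S100P, above background on 1 of the 2 arrays, was lower (-5.65 ± 0.58), and the nuclear receptor PPARG was at least 28.4-fold lower (second probe -2.65). The counts reached 585 higher and 812 lower. Wnt target and stem-cell genes were lower (median -0.56, adjusted p = 0.00422, 5 of 22 members lower and DKK1 higher by 2.06), with LRIG1 at least 10.0-fold lower and CD44 at -4.07 ± 0.15 on 1 probe and -0.315 on another, and adjusted p = 0.164 with an estimated correlation. Among the lists, epithelial junction genes were higher (median 0.63, adjusted p = 0.000886, 6 of 31 members), led by the tight-junction protein CLDN4 (1.58 ± 0.21), with adjusted p = 0.213 with an estimated correlation. EGFR ligand and MAPK output genes were lower (median -0.54, adjusted p = 0.0172, 5 of 23 members, 6 adjusted over the list alone), led by ETV1 (at least 2.89-fold) and the phosphatase DUSP6 (-1.70 ± 0.31), with adjusted p = 0.424 with an estimated correlation. That call ended without the first HCT-15 array (median -0.26), and the median was -0.85 without the second.

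In HCT116 GTSF1, a germ-line factor above background on 2 of the 30 other arrays, was at least 358-fold higher (n = 2). The kinase anchor AKAP12 (6.10 ± 0.48, SE), the retinol-binding protein RBP7 (at least 43.3-fold) and CST6 (5.23 ± 0.32) were higher. The oxidoreductase SCCPDH was at least 129-fold and TSPAN8 at least 110-fold lower. Probes called were 1001 higher and 785 lower. Enterocyte genes were lower (median -0.55, adjusted p = 0.000257, 8 of 24 members), led by LGALS4 (at least 18.3-fold) and the microvillus protein VIL1 (at least 10.3-fold), with adjusted p = 0.101 with an estimated correlation. Mesenchymal genes were higher (median 0.29, adjusted p = 0.00439, 6 of 15 members higher and 1 lower), led by the transcription factor TWIST1 (at least 9.12-fold) and the caveolin CAV2 (2.88 ± 0.32), with adjusted p = 0.10 with an estimated correlation. Targets of p53 were higher (median 0.28, adjusted p = 0.0130, 7 of 31 members), led by CDKN1A (2.76 ± 0.45) and TP53INP1 (at least 3.67-fold), with adjusted p = 0.197 with an estimated correlation and a median of 0.44 without the first HCT116 array. Hypoxia and glycolysis genes were higher (median 0.55, adjusted p = 0.0281, 6 of 25 members), among them ADM (2.86 ± 0.35) and BNIP3 (at least 19.7-fold, second probe -0.0902), with adjusted p = 0.451 with an estimated correlation. The median was 0.87 without the first HCT116 array, and the call ended without the second (0.18). Xenobiotic genes were lower (median -0.53, adjusted p = 0.0419, 11 of 30 members lower and 2 higher), with GPX2 at least 18.9-fold lower and the pump ABCC2 at least 15.1-fold higher, and adjusted p = 0.314 with an estimated correlation, and the call ended with median scaling (-0.50).

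In HT-29 the membrane protein TM4SF4 was at least 88.8-fold higher (n = 2), the interferon-induced tetherin BST2 at least 36.8-fold, SPINK1 by 5.39 ± 0.48 (SE) and the water channel AQP3 by 5.07 ± 0.34. TUBB6 was at least 35.0-fold and the actin-binding CNN3 at least 30.7-fold lower. Higher probes numbered 1223 and lower ones 741. Interferon-response genes were higher (median 1.09, adjusted p = 5.33e-06, 16 of 33 members, 17 adjusted over the list alone), led after BST2 by IFI44 (at least 30.0-fold) and IFI27 (4.68 ± 0.42), with adjusted p = 0.50 with an estimated correlation. That median was 1.67 without the first HT-29 array and 0.63 without the second. Genes of epithelial junctions were higher (median 0.31, adjusted p = 0.000799, 11 of 31 members higher and 1 lower), led by SPINT2 (2.28 ± 0.18) and GRHL2 (1.91 ± 0.19), with adjusted p = 0.197 with an estimated correlation. Cancer-testis genes were lower (median -0.34, adjusted p = 0.00606, 2 of 17 members), MAGEA12 at least 2.98-fold and MAGEB2 by a log2 difference of -1.32 ± 0.24, with adjusted p = 0.10 with an estimated correlation. Genes of NF-kappaB and chemokines were higher (median 0.49, adjusted p = 0.0239, 7 of 21 members higher and 2 lower, 8 and 2 adjusted over the list alone), led by the prostaglandin synthase PTGS2 (at least 13.1-fold), with adjusted p = 0.410 with an estimated correlation. Cholesterol synthesis genes were lower (median -0.60, adjusted p = 0.0240, 5 of 18 members), led by CYP51A1 (-1.76 ± 0.22), with adjusted p = 0.560 with an estimated correlation. Neuroendocrine genes were lower (median -0.29, adjusted p = 0.0429, 3 of 25 members), led by the decarboxylase DDC (at least 4.23-fold), with adjusted p = 0.263 with an estimated correlation, and this call ended with median scaling (-0.30). Without the second HT-29 array the last 3 calls ended, at medians of 0.15, -0.45 and -0.27 in this order.

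In LoVo the activin antagonist FST was at least 144-fold higher (n = 2, second probe 4.18), the calcium-binding CALB1 at least 145-fold, the adhesion molecule CEACAM6 at least 61.5-fold and IL33 by 5.86 ± 0.29 (SE). The respiratory-chain protein COX7A2L (-5.06 ± 0.22) and the quinone reductase NQO1 (-5.01 ± 0.25) were lower, each above background on 1 of the 2 arrays. In total 985 probes were higher and 1283 lower. Interferon-response genes were higher (median 1.99, adjusted p = 3.43e-08, 22 of 33 members), led by IFIT1 (4.73 ± 0.62), OASL (4.65 ± 0.32) and IFI27 (4.10 ± 0.42), with adjusted p = 0.400 with an estimated correlation. The median was 0.80 without the first LoVo array (IFIT1 2.92) and 3.06 without the second. Enterocyte genes were higher (median 0.35, adjusted p = 0.0269, 6 of 24 members higher and 2 lower), led by the steroid dehydrogenase HSD17B2 (at least 24.9-fold) and the cadherin CDH17 (3.24 ± 0.26), with adjusted p = 0.361 with an estimated correlation, and the call ended without the second LoVo array (0.30). Proliferation genes were lower (median -0.65, adjusted p = 0.0112, 12 of 40 members), led by the spindle protein TPX2 (-1.88 ± 0.48), with adjusted p = 0.787 with an estimated correlation. Without the first LoVo array that median was -0.14 and neither the list nor TPX2 (-1.30) was called, and without the second the median was -1.27.

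In LS180 the metallothionein MT1H was at least 62.8-fold higher (n = 2), the secretory lectin ZG16B at least 57.8-fold, CALB1 at least 45.5-fold and IL33 by 5.65 ± 0.29 (SE). CRNDE, a noncoding RNA known to be raised in colorectal neoplasia, was at least 90.9-fold lower than in the other lines, all of which had it above background, and the signalling regulator RGS19 was at least 26.0-fold lower. Called probes were 800 higher and 766 lower. Goblet-cell genes were higher (median 1.17, adjusted p = 5.33e-06, 8 of 19 members higher and 1 lower, 10 and 1 adjusted over the list alone), and this call held at adjusted p = 0.0428 with an estimated correlation, but ended with only probes above background on all 32 arrays (median 0.89). The mucus protein FCGBP (4.86 ± 0.34), AGR2 (4.11 ± 0.26) and MUC2 (at least 5.53-fold) led it. Enterocyte genes were higher (median 0.15, adjusted p = 0.000886, 7 of 24 members), led by LGALS4 (5.18 ± 0.23) and the fatty acid carrier FABP2 (at least 17.2-fold), with adjusted p = 0.140 with an estimated correlation and a median of 0.52 without the second LS180 array. Wnt target and stem-cell genes were higher (median 0.54, adjusted p = 0.000815, 8 of 22 members higher and 1 lower), led by DKK1 (2.96 ± 0.29), with adjusted p = 0.122 with an estimated correlation and a median of 0.30 without the second LS180 array. HOX genes, which pattern the body axis, were lower (median -0.48, adjusted p = 0.00101, 5 of 18 members), led by HOXA2 (-2.67 ± 0.21) and HOXC9 (at least 3.57-fold), with adjusted p = 0.164 with an estimated correlation.

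In SW48 the fatty acid receptor CD36 was at least 242-fold higher (n = 2), the epidermal proteases KLK7 by 6.79 ± 0.39 (SE) and KLK5 at least 60.8-fold, and the noncoding RNA MIR31HG by 6.64 ± 0.25. AGR2 was at least 61.1-fold lower and EID1, an inhibitor of differentiation, at least 26.1-fold lower (second probe -1.05). There were 943 higher and 877 lower probes. Enterocyte genes were lower (median -0.22, adjusted p = 0.0332, 5 of 24 members lower and 1 higher), led by LGALS4 (at least 16.7-fold) and VIL1 (at least 9.39-fold), with adjusted p = 0.377 with an estimated correlation, and the call ended without the first SW48 array (-0.29). Interferon-response genes were lower (median -0.62, adjusted p = 0.0269, 6 of 33 members lower and 1 higher), led by IFI27 (-3.41 ± 0.42) and HERC5 (at least 5.88-fold), with adjusted p = 0.754 with an estimated correlation. Xenobiotic genes were lower (median -0.31, adjusted p = 0.0446, 9 of 30 members lower and 3 higher), with GPX2 at least 17.2-fold and the DNA repair enzyme MGMT at least 14.3-fold lower, and adjusted p = 0.323 with an estimated correlation. Both of these calls ended without the second SW48 array, at medians of -0.61 and -0.30, and the xenobiotic call also with cyclic loess (-0.34). With only probes above background on all 32 arrays the xenobiotic median turned to 0.41.

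In SW480 the basal keratin KRT5, above background on 2 of the 30 other arrays, was at least 140-fold higher (n = 2). The myosin MYH7B (at least 105-fold), the tight-junction protein CLDN11 (at least 71.5-fold) and the secreted NELL2 (at least 58.5-fold) were higher, while RAB25 was at least 71.7-fold and AGR2 at least 59.8-fold lower. The called probes were 1766 higher and 1167 lower, and 2021 and 852 with cyclic loess. Goblet-cell genes were lower (median -0.81, adjusted p = 0.00652, 5 of 19 members lower and TFF3 higher by 2.05), led after AGR2 by AGR3 (at least 3.30-fold), with adjusted p = 0.164 with an estimated correlation. Enterocyte genes were lower (median -0.60, adjusted p = 0.0104, 5 of 24 members lower and VIL1 higher by 1.86), led by LGALS4 (-3.55 ± 0.23, SE) and DPP4 (at least 5.38-fold), with adjusted p = 0.252 with an estimated correlation. Epithelial junction genes were lower (median -0.62, adjusted p = 0.0332, 9 of 31 members, with 1 higher when adjusted over the list alone), led after RAB25 by GRHL2 (at least 4.18-fold), with adjusted p = 0.400 with an estimated correlation, and the call ended without the second SW480 array (-0.50). NF-kappaB and chemokine genes were lower (median -0.68, adjusted p = 0.0408, 5 of 21 members), led by the cytokine IL18 (at least 19.3-fold), with adjusted p = 0.451 with an estimated correlation, and this call ended without either SW480 array at an unchanged median of -0.68. With the array series as a block the list calls held, at -0.75, -0.61, -0.73 and -1.10 in this order. The block rests on HCT-8, the only line in both series, so it cannot decide for SW480 or SW620. Calls of single members ended, among them VIL1 (1.58), CA4 (-1.17), TFF3 (1.72), GALNT5 (-0.38), CDS1 (-1.19) and 3 of the 5 NF-kappaB members, IL32 (-2.25), IL6 (-1.24) and TRAF1 (-1.78).

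In SW620 CLDN11 was at least 92.0-fold higher (n = 2), the secreted serpin SERPINF1 at least 61.8-fold, the transporter SLC43A3 at least 37.3-fold and the stem-cell factor SOX2, above background on 1 of the 30 other arrays, at least 36.8-fold. RAB25 was at least 51.2-fold and the vesicle protein TMED3 at least 30.2-fold lower. Counts of called probes were 1228 higher and 1449 lower, 2677 together, and 1720 with array quality weights. By list, epithelial junction genes were lower (median -1.22, adjusted p = 5.33e-06, 18 of 31 members), led after RAB25 by the tight-junction protein CLDN7 (at least 8.77-fold) and CDS1 (-2.91 ± 0.26, SE), with adjusted p = 0.101 with an estimated correlation. The call of the desmosomal DSP (-1.86) ended with the array series as a block (-2.02).

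In SW948 the guanylin receptor GUCY2C was at least 21.6-fold and REG1A at least 19.4-fold higher (n = 2), LGALS4 by 4.53 ± 0.23 (SE) and the LRAT-domain protein LRATD1 by 4.51 ± 0.21. The leukaemia-associated factor MLF1 was at least 21.1-fold lower (second probe -1.87), and the motility-associated S100A4 was lower (-4.24 ± 0.29). The line had 1598 probes higher and 1017 lower. Enterocyte genes were higher (median 0.07, adjusted p = 0.00172, 10 of 24 members), led by LGALS4, DPP4 (4.12 ± 0.35) and CDH17 (3.99 ± 0.26), with adjusted p = 0.164 with an estimated correlation. The median was 0.16 without the first SW948 array and 0.01 without the second. Epithelial junction genes were higher (median 0.39, adjusted p = 0.0408, 10 of 31 members higher and 1 lower), led by ELF3 (2.35 ± 0.28), with adjusted p = 0.413 with an estimated correlation. Mesenchymal genes were lower (median -0.33, adjusted p = 0.0428, 2 of 15 members, S100A4 and CCN1), with adjusted p = 0.164 with an estimated correlation. Without the second SW948 array both of these calls ended (0.23 and -0.27), as did that of CCN1 (-1.12 against -1.39).

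In T84 BST2 was at least 30.0-fold and GUCY2C at least 20.2-fold higher (n = 2), and the eicosanoid receptor OXER1 by 4.67 ± 0.21 (SE). The mitophagy receptor BNIP3 was at least 21.6-fold higher on 1 probe, and 0.192 on its second. The kinase FYN, above background on 1 of the 2 arrays, was lower (-4.86 ± 0.28), a call that 1 of its 2 other probes shared, and GAL was at least 22.7-fold lower. Probes called were 1184 higher and 670 lower. Enterocyte genes were higher (median 0.25, adjusted p = 0.00179, 9 of 24 members), led by LGALS4 (4.10 ± 0.23) and VIL1 (3.02 ± 0.31), with adjusted p = 0.164 with an estimated correlation. Genes of epithelial junctions were higher (median 0.50, adjusted p = 0.00150, 9 of 31 members), led by the claudin CLDN3 (3.19 ± 0.25), with adjusted p = 0.242 with an estimated correlation. Interferon-response genes were higher (median 0.64, adjusted p = 0.000977, 11 of 33 members higher and 1 lower, 12 and 1 adjusted over the list alone), led after BST2 by IFITM1 (4.51 ± 0.78) and IFI27 (4.32 ± 0.42), against IFITM3 (-3.22 ± 0.39), with adjusted p = 0.627 with an estimated correlation. That call ended without the first T84 array (0.15), and the median was 1.08 without the second. Mesenchymal genes were lower (median -0.53, adjusted p = 0.0240, 2 of 15 members, CAV2 by -3.02 ± 0.32 and S100A4 by -1.52 ± 0.29), with adjusted p = 0.136 with an estimated correlation, and the call ended without the second T84 array (-0.53). Cancer-testis genes were lower (median -0.30, adjusted p = 0.0238) with 1 of 17 members called, MAGEA12 (at least 2.92-fold), and adjusted p = 0.129 with an estimated correlation.

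At the preset correlation, epithelial junction genes were called higher in 7 lines and lower in 3. The 3 low lines lower the mean set against the 7, so those calls may partly rest on this. Higher and lower calls were 5 and 4 for enterocyte, 3 and 3 for interferon, 2 and 4 for cancer-testis and 1 and 3 for xenobiotic genes. With an estimated correlation camera called only epithelial junction genes in COLO320, cancer-testis genes in CX-1 and goblet-cell genes in LS180. Paneth-cell, DNA mismatch repair, fibroblast, leukocyte and endothelial genes were called by camera in 0 lines and 0 pairs, with 2, 2, 1, 2 and 1 line tests and 0, 1, 2, 0 and 2 pair tests at an unadjusted p below 0.05. Their members still differed between lines by the F test, 7 of 8 Paneth-cell, 13 of 15 mismatch repair, 9 of 11 fibroblast, 7 of 8 leukocyte and 4 of 5 endothelial genes. Of the 352 tests over lines, 26 were called higher and 30 lower. The array identifiers put the SW480 and SW620 arrays and the first HCT-8 array in 1 array series (5 arrays) and all others in another (27). With the series as a block 66 tests over lines were called, and 2151 probes in SW480, 2228 in SW620 and 2037 in HCT-8. Among the 27 arrays alone, 52 of the 60 called list tests that could be repeated were called again, and 0 turned direction. A filter on all 32 arrays ended 53 of the 65 list calls and turned the camera direction of 2 others. Among the 53 the median changed sign for xenobiotic genes in HCT116 (0.05), epithelial junction genes in SW948 (-0.09) and enterocyte genes in T84 (-0.05).

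Setting the floor at 1 ended 17 list calls: cancer-testis genes in CloneA, HCT-8 (-0.55), HT-29 (-0.61) and T84 (-0.37), xenobiotic genes in COLO205 (0.65), HCT116 (-0.58), SW48 (-0.29) and HCT-15 against DLD-1 (-0.29), and enterocyte genes in SW48 (-0.21), SW480 (-0.45) and CX-1 against HT-29 (0.27). Others were mesenchymal genes in SW948 (-0.33) and T84 (-0.57), epithelial junction genes in SW948 (0.44), hypoxia genes in HCT116 (0.55), and neuroendocrine (-0.40) and NF-kappaB genes (0.49) in HT-29. Leaving out the filter on dim probes ended 10: enterocyte genes in CloneA (-0.07), COLO205 (0.14), SW48 (-0.16) and CX-1 against HT-29 (0.16), xenobiotic genes in COLO205 (0.23), HCT116 (-0.40) and SW48 (-0.30), cancer-testis genes in COLO320, NF-kappaB genes in SW480 (-0.40) and mesenchymal genes in SW948 (-0.21). Projecting out trends between arrays ended 12: xenobiotic genes in COLO205 (0.30), HCT116 (-0.53), SW48 (-0.34) and HCT-15 against DLD-1 (-0.23), neuroendocrine (-0.28), cholesterol (-0.42) and NF-kappaB genes (0.39) in HT-29, enterocyte (0.32) and proliferation genes (-0.22) in LoVo, EGFR ligand and MAPK genes in HCT-15 (-0.39), NF-kappaB genes in SW480 (-0.58) and epithelial junction genes in SW948 (0.26). With contaminated spots missing, enterocyte genes in CloneA (-0.20), COLO205 (0.25) and CX-1 against HT-29 (0.27), xenobiotic genes in COLO205 (0.31) and SW48 (-0.32), NF-kappaB genes in SW480 (-0.69) and epithelial junction genes in SW948 (0.40) were not called. Among the 27 arrays, enterocyte genes in COLO205 (0.17) and LoVo (0.39), xenobiotic genes in COLO205 (0.23), epithelial junction genes in DLD-1 (0.42) and SW948 (0.23), neuroendocrine (-0.27) and NF-kappaB genes (0.33) in HT-29 and mesenchymal genes in SW948 (-0.27) were not called. With log2(value + 50), xenobiotic genes in SW48 (-0.26), mesenchymal (-0.25) and epithelial junction genes (0.21) in SW948 and cancer-testis genes in T84 (-0.17) were not called.

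Medians of some gene groups moved by over 1.5 times although the call held. Without the filter on dim probes cancer-testis genes had -0.01 in CX-1 (a changed sign), -0.31 in HCT-8, -0.19 in T84 and 0.35 in CX-1 against HT-29. Enterocyte genes then had -0.33 in HCT116, 0.04 in LS180, -0.21 in SW480, 0.00 in SW948 and 0.06 in T84, mesenchymal genes 0.11 in HCT116 and -0.23 in T84, NF-kappaB genes 0.13 in HT-29 and -0.27 in CX-1 against HT-29, Wnt target genes 0.33 in LS180 and goblet-cell genes 0.19 in CX-1. With the floor at 1 the medians were 0.17 for cancer-testis genes in CX-1, 1.06 for Wnt target genes in LS180, 0.35 for enterocyte genes in SW948 and -0.87 for antigen presentation genes in CloneA against DLD-1. Epithelial junction genes in HT-29 had 0.17 with median scaling, and cyclic loess gave enterocyte genes 0.16 in SW948 and 0.17 in CX-1 against HT-29, and xenobiotic genes -0.13 in HCT-15 against DLD-1. Among the 27 arrays goblet-cell genes in CX-1 had 0.15, enterocyte genes 0.07 in LS180 and 0.03 in SW948, and epithelial junction genes in T84 0.25.

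Single genes had smaller log2 differences without 1 array, and kept their calls. Such were SPRR1A in COLO205 (6.01 without the second array, against 6.75), RASIP1 (3.03 without the second) and S100P (-4.48 without the first) in HCT-15, IL33 in LS180 (4.93 without the first), MIR31HG in SW48 (5.98 without the second) and REG1A in SW948 (3.92 without the first). So were, of interferon-response genes, IFI27 (3.95) and IFI44 (4.26) in HT-29 without the second array, IFI27 (3.02) and OASL (3.50) in LoVo without the first, IFI27 (3.47) and IFITM1 (3.79) in T84 without the first and IFITM3 (-2.38) without the second. CAV2 in T84 was -2.31 without the first array.

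**Figure D4:**
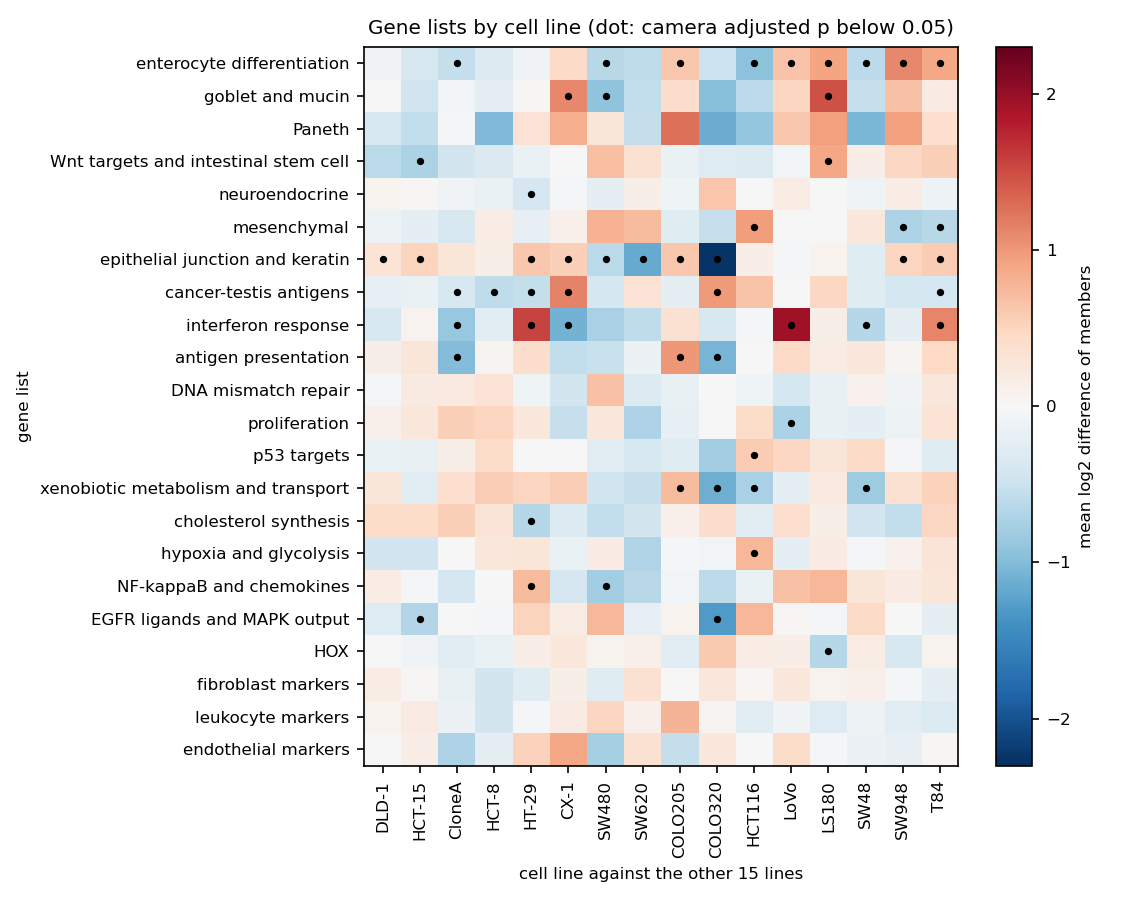
Mean log2 difference of the measured members of the 22 gene lists in each line against the other 15, with a dot where the camera test was called (adjusted p below 0.05, preset correlation). Pairs of lines are not drawn. By the median, which is not drawn, epithelial junction genes were lowest in COLO320 (-1.38).

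SW620 and SW480, from a metastasis and the primary tumour of 1 patient, were compared directly. The stem-cell factor SOX2 was at least 39.0-fold higher in SW620 (n = 2 against 2), the secreted CYTL1 at least 26.6-fold and the centrosomal CEP15 at least 23.7-fold. The imprinted PEG10 was higher by 3.94 ± 0.24 (SE), the transcription factors SALL2 and FOXP1 at least 12.2-fold and 9.72-fold, CALB1 at least 9.71-fold, the adhesion molecule ICAM2 by 3.38 ± 0.34 and the necroptosis effector MLKL by 3.29 ± 0.41. Lower in SW620 were the keratins KRT5 (at least 95.6-fold), KRT23 (at least 49.2-fold) and KRT13 (at least 23.4-fold), the collagen COL4A1 (at least 16.9-fold), the cyclin CCND2 (at least 20.8-fold), the iron-binding LCN2 (at least 22.5-fold, adjusted p = 0.000975, second probe -3.32) and the arginine-metabolising DDAH1 (at least 15.1-fold). SPINK1 (-6.18 ± 0.66), NELL2 (-5.83 ± 0.21) and the neuropeptide CALCB (-4.89 ± 0.48) were lower too, each above background on 1 of the 2 SW620 arrays. By limma 4536 probes (28.4%) were called, 2068 higher and 2468 lower, and camera called 0 of 22 lists, 7 at an unadjusted p below 0.05. With median scaling the median of all probes shifted by 0.15. IFI35 was called (3.43 ± 1.10, adjusted p = 0.0152) but only 0.55 without the first SW620 array and 6.32 without the second, and its call also ended without the first (3.51) or the second SW480 array (3.36). SALL2 was 1.46 higher on the log2 scale without the first SW620 array and 5.77 without the second, against 3.61 with both. LCN2 was lower by a log2 difference of -4.03 without the first SW480 array (adjusted p = 0.0277) and -6.22 without the second, against -5.13. CALCB was -4.02 without the first SW620 array, and without the second ICAM2 was 2.62, KRT5 -5.87 and KRT23 -5.04, against -6.66 and -5.70 for these keratins. All 4 arrays belonged to the smaller array series, whose 5 arrays alone gave 595 called probes and ended 9 of the 20 named calls, SALL2, IFI35, ICAM2, MLKL, KRT5, KRT23, LCN2, CALCB and DDAH1, at unchanged log2 differences.

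CX-1 and HT-29 share a recorded origin and were compared directly. The cancer-testis genes PAGE5 (at least 107-fold) and MAGEA12 (at least 101-fold) and the adhesion molecule CEACAM6 (at least 108-fold) were higher in CX-1 (n = 2 against 2), as were AGR3 (6.21 ± 0.41, SE), ODAM (5.90 ± 0.44) and the Wnt inhibitor DKK1 (5.73 ± 0.40). AGR3 and ODAM were above background on 1 of the 2 HT-29 arrays. The interferon-induced genes IFI27 (-6.70 ± 0.58), BST2 (at least 83.9-fold), IFI44 (at least 55.5-fold) and IFITM1 (at least 38.6-fold, adjusted p = 0.00136) were lower in CX-1, as were TM4SF4 (-6.97 ± 0.23), above background on 1 of the 2 CX-1 arrays, and AQP3 (-5.73 ± 0.47). Without the second HT-29 array the log2 differences were -4.43 for IFITM1 (adjusted p = 0.0432, against -5.52), -5.26 for IFI44 (against -6.05) and -5.97 for IFI27. CEACAM6 was 5.82 without the first CX-1 array (against 6.78), and ODAM 5.18 without the second. In this pair 1364 probes (8.54%) were called, 553 higher and 811 lower, and 837 without the second HT-29 array. Interferon-response genes were lower (median -2.21, adjusted p = 1.09e-14, 18 of 33 members, 19 adjusted over the list alone), with adjusted p = 0.596 with an estimated correlation. Cancer-testis genes were higher (median 0.60, adjusted p = 2.19e-09, 6 of 17 members), and this call held at adjusted p = 0.000267 with an estimated correlation, but ended with only probes above background on all 32 arrays (median 0.44).

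Other gene groups differed between CX-1 and HT-29 as well. Goblet-cell genes were higher in CX-1 (median 0.62, adjusted p = 0.000597, 4 of 19 members), led after AGR3 by the regenerating protein REG4 (7.97-fold, n = 2, and log2 2.41 without the second CX-1 array), with adjusted p = 0.134 with an estimated correlation. Genes of NF-kappaB and chemokines were lower (median -0.66, adjusted p = 0.000235, 6 of 21 members), led by PTGS2 (-3.54 ± 0.40) and the chemokine CXCL10 (at least 6.68-fold), with adjusted p = 0.532 with an estimated correlation. That median was -1.21 without the first HT-29 array and -0.32 without the second. Antigen presentation genes were lower (median -0.24, adjusted p = 0.0145, 5 of 19 members, 6 adjusted over the list alone), led by PSMB8 (at least 29.1-fold) and PSMB9 (at least 16.3-fold, log2 -4.27, and -3.53 without the second HT-29 array), with adjusted p = 0.832 with an estimated correlation. The call ended without the second CX-1 array (-0.05) or the second HT-29 array (-0.12), and the median was -0.53 without the first CX-1 array. Proliferation genes were lower (median -0.71, adjusted p = 0.0145, 5 of 40 members, 6 adjusted over the list alone), led by the topoisomerase TOP2A (-1.99 ± 0.65), with adjusted p = 0.898 with an estimated correlation. The call ended without the first CX-1 array (-0.13, TOP2A -1.03) or the second HT-29 array (-0.49, TOP2A -1.63), and the median was -1.39 without the second CX-1 array. TOP2A was also not called without the first HT-29 array (-2.35), with median scaling (-1.90) or with the array series as a block (-1.99). Enterocyte genes were higher (median 0.27, adjusted p = 0.0408, 4 of 24 members higher and 1 lower, 5 and 1 adjusted over the list alone), led by DPP4 (2.96 ± 0.48, and 2.25 without the first CX-1 array), with adjusted p = 0.631 with an estimated correlation, and the call ended without the first CX-1 array (0.20), without the second HT-29 array (0.35) and with median scaling (0.27).

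**Figure D5:**
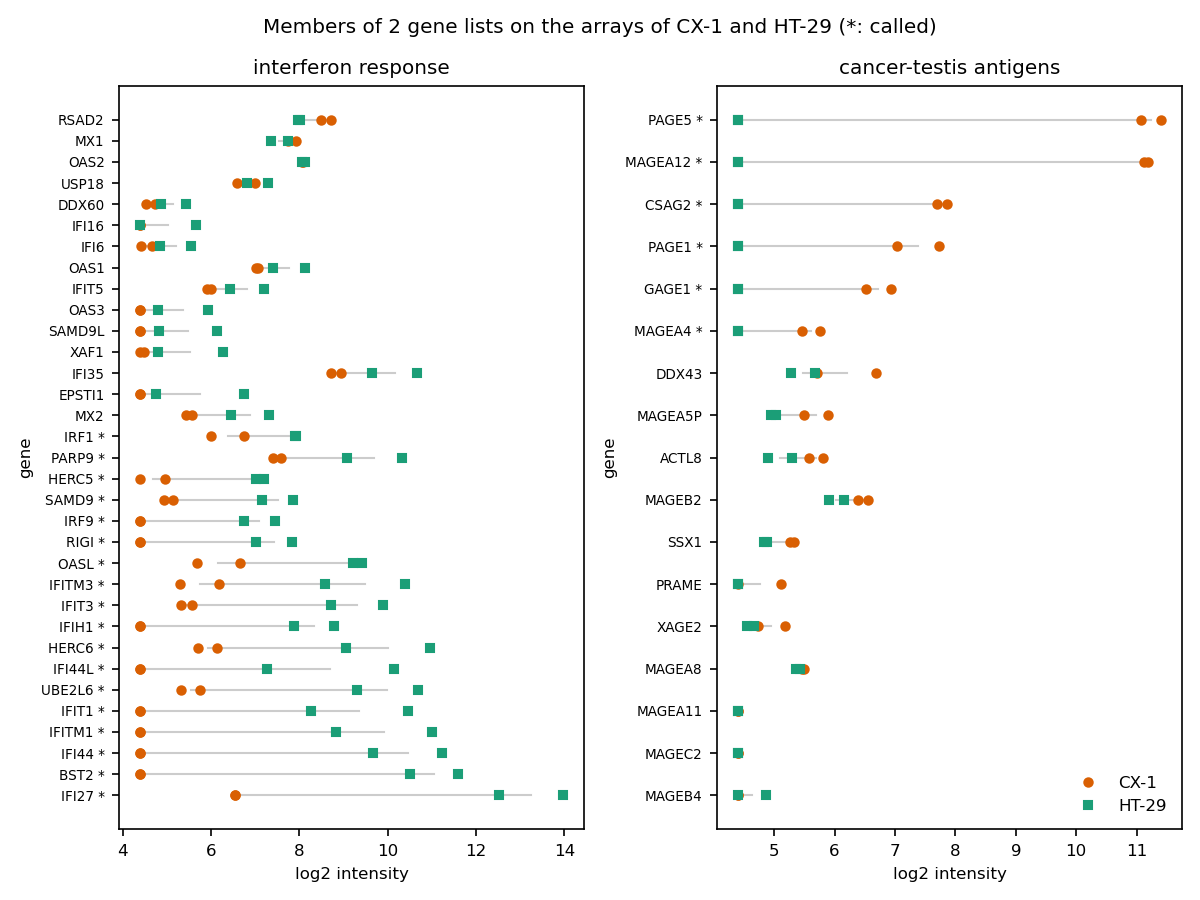
Log2 signal on each of the 2 CX-1 and 2 HT-29 arrays for members of the interferon-response and cancer-testis lists, with an asterisk where the difference was called. Of 33 interferon-response genes 18 were called lower in CX-1, and of 17 cancer-testis genes 6 were called higher.

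HCT-15 and DLD-1 are recorded as 1 origin and differed least among the pairs. RAMP1, an accessory protein of the calcitonin-family receptors, was higher in HCT-15 by 5.33 ± 0.34 (SE, n = 2 against 2), DKK1 at least 26.7-fold and the cytokine IL32 by 4.75 ± 0.51. The iron-sulfur scaffold NFU1 was at least 24.2-fold lower in HCT-15, with a value on 1 of its 2 arrays, PPARG at least 21.1-fold (second probe -1.96) and the protease inhibitor CST7 at least 18.5-fold. S100P was lower (-6.58 ± 0.79), above background on 1 of the 2 HCT-15 arrays, and was -5.29 without the first DLD-1 array and -5.42 without the first HCT-15 array. IFITM1 was higher by 4.64 ± 1.06 (adjusted p = 0.0124), a call that ended without any 1 of the 4 arrays (4.77 and 4.51 without the first and second DLD-1 array, 4.86 and 4.41 without the first and second HCT-15 array). Of 551 called probes (3.45%), 263 were higher and 288 lower. Without the first DLD-1 array the count was 315, without the second 327, and without the first HCT-15 array 480, split into 307 higher and 173 lower. Xenobiotic genes were lower (median -0.21, adjusted p = 0.0408, 3 of 30 members lower and 1 higher, 4 and 1 adjusted over the list alone), led by AKR1C3 (-4.31 ± 0.62), with adjusted p = 0.567 with an estimated correlation. That call ended without the first DLD-1 array (-0.20), the first (-0.11) or the second HCT-15 array (-0.20), and with median scaling (-0.24).

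HCT-8, also tied to DLD-1 in cell line records, differed from it widely. IFI27 was higher in HCT-8 by 6.91 ± 0.58 (SE, n = 2 against 2), the adipogenesis-associated ADIRF at least 85.9-fold, AKR1B10 by 5.87 ± 0.80 and the inflammasome adaptor PYCARD at least 36.6-fold. PCP4 (-4.73 ± 0.57) was lower and RBMS1 at least 18.7-fold lower (second probe -1.75). The surface sialoglycoprotein CD24 (-4.21 ± 0.50) and the cytoskeletal regulator DPYSL3 (-4.10 ± 0.47) were lower, each above background on 1 of the 2 HCT-8 arrays. AKR1B10 was 4.85 without the second DLD-1 array, and ADIRF 5.78 without the first HCT-8 array (log2, against 6.55). By limma 4037 probes (25.3%) were called, 2223 higher and 1814 lower, and 2629 and 1067 with cyclic loess. Camera called 0 of 22 lists, with 1 at an unadjusted p below 0.05. With median scaling the median of all probes shifted by -0.10. The count was 3596 with the array series as a block and 3753 among the 27 arrays of the larger series.

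CloneA, recorded as a subclone of the same origin, was compared with DLD-1. REG1A was at least 62.7-fold higher in CloneA (n = 2 against 2), ODAM higher by 3.85 ± 0.44 (SE) and the nucleosome-binding HMGN5 by 3.70 ± 0.55. GAL was at least 109-fold, PLAAT3 at least 103-fold, PSMB8 at least 43.7-fold and the lysosomal enzyme GALC at least 38.9-fold lower. The stress-response gene DDIT4 was higher by 4.01 ± 1.10 on 1 probe (adjusted p = 0.0142) and -0.696 on its second, and the call ended without the first (3.66) or the second CloneA array (4.36) and without the first DLD-1 array (3.63). In all 1718 probes (10.8%) were called, 1069 higher and 649 lower, and 971 without the first DLD-1 array. Antigen presentation genes were lower (median -0.41, adjusted p = 0.00352, 5 of 19 members), led after PSMB8 by PSMB9 (at least 19.1-fold), with adjusted p = 0.722 with an estimated correlation.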

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

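Among the tests in this part, those of the array series and of mislabelling for HCT-8 were chosen after the result was seen, as were the projection of trends between arrays and the separate fits of the array series. The test of mislabelling replaced a first version that had been seen, on 3 to 7 genes per set below background in DLD-1 and HCT-15, in which the COLO320 set had a higher share in the line left out (50%) than in HCT-8 (33.3%) and the other 11 sets had a lower one.

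Control spots for transcripts added during labelling, which no comparison used, carried signal on 30 of the 32 arrays. Their array medians ran from 6.96 (SW948, first array) to 90.1 in units of normalized intensity, and the median over all 32 arrays was 40.1. On the first DLD-1 array the median was 0.0952 and on the second T84 array 0.0894, within the range of the negative controls, whose array medians were at most 0.227. The labels do not mention these additions.

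HCT-8 correlated at -0.146 with DLD-1, to which cell line records tie it, and at 0.271 with SW948. After the 2 leading trends between arrays of a line were projected out, its r with DLD-1 was -0.151 and its highest with a line of no recorded tie 0.273, which argues against such a trend. The second HCT-8 array, of the same array series as DLD-1, correlated at -0.126 with DLD-1 and 0.231 with SW948, which argues against the array series. In 12 sets of 14 to 20 genes particular to DLD-1 and HCT-15, each leaving out 1 unrelated line, HCT-8 lay nearer to these lines on 29.4% to 45% of the genes and CloneA on 41.2% to 60%. The share of HCT-8 was above that of the line left out in 11 of the 12 sets and equal to it in 1 (LoVo, 31.6%), which leans against mislabelled arrays, but the sets are small and overlap and the lowest HCT-8 share lay below the highest of a line left out, so mislabelling and a divergence of the line, which was not tested, cannot be told apart.

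SW620 and SW480 differed in 4536 probes although both come from 1 patient. Without the first SW620 array, which departs most from its mate, the count was 5607, which argues against that array as the source. After the 2 leading trends were projected out it was 4100, which argues against those trends as the whole of it. The 4 arrays share 1 array series, so a difference between series does not separate the lines. Differences between primary tumour and metastasis, or acquired in culture, stay open and were not tested.

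Interferon-response genes were lower in CX-1 than in HT-29 by a median log2 difference of -2.21, with 18 of 33 members called and adjusted p = 0.596 with an estimated correlation. In 10000 random lists matched on mean level the central 95% of medians ran from -0.21 to 0.27 and 0 were as low, which argues against a general shift between the arrays. Over the 4 fits that each left out 1 array the smallest median was -1.59, without the second HT-29 array, which argues against 1 deviating array. Culture conditions, an infection and a difference between the lines stay open, and no biological explanation was tested.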

How the results depend on the processing

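The log2(value + 50) scale, the fits without the first SW620 and first HCT-15 arrays, the fits of 1 array series alone and the projection of 2 trends between arrays were chosen after seeing the data, and all other alternatives were planned. Of 637 alternative values of 26 results, the counts and the similarity together, 546 stayed within 1.5 times the value given or on its side of the threshold, 71 were weaker, 20 stronger and 0 reversed. Of 8780 values of 476 named gene differences 268 lost their call and 0 reversed, and of 1118 values of 65 called list tests 218 lost it and 2 reversed in camera direction. Signal over background limits what can be seen: 11.2% of values lay at the floor, and differences of genes near it depend on the floor or offset. The experiment as a block, run for 24 of these counts, kept each within 1.5 times, with 4532 probes in SW620 against SW480 and 56 list tests over lines. The experiment numbers do not pair arrays between lines, since the correlations of within-line differences over 120 line pairs ran from -0.304 to 0.399 with a median of 0.00263. The difference in similarity stayed past its threshold throughout, from 0.200 (Spearman) to 0.531 (the 1000 probes of largest SD). Leaving out both arrays in doubt gave 5648 probes in SW620 against SW480 and 564 in HCT-15 against DLD-1.

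With an estimated correlation 3 list tests over lines and 1 over pairs were called in place of 56 and 9, and the cause was not tested. Array quality weights, lowest for SW620 (0.282 per array), gave it 1720 probes against 2677. The 5 arrays of the smaller series alone gave 595 probes in SW620 against SW480 in place of 4536. That fit has fewer arrays, and its error rests on SW480 and SW620 alone. Leaving out 1 array gave 315 to 746 probes in HCT-15 against DLD-1 (551 with all), 971 to 1580 in CloneA against DLD-1 (1718) and 837 to 1427 in CX-1 against HT-29 (1364), fits with fewer arrays.

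With log2(value + 50), which shrinks differences at low signal, the called probes were 742 (CloneA), 1205 (COLO205), 1739 (COLO320), 758 (CX-1), 727 (DLD-1), 995 (HCT-8), 659 (HCT-15), 961 (HCT116), 1084 (HT-29), 1148 (LoVo), 770 (LS180), 937 (SW48), 1452 (SW480), 1414 (SW620), 1441 (SW948) and 942 (T84) for lines, and 2497 (SW620 against SW480), 734 (CX-1 against HT-29), 301 (HCT-15 against DLD-1), 2303 (HCT-8 against DLD-1) and 865 (CloneA against DLD-1) for pairs. Without a fold threshold, which admits smaller differences, they were 4084 (CloneA), 5320 (COLO205), 6460 (COLO320), 4028 (CX-1), 5165 (DLD-1), 6394 (HCT-8), 4235 (HCT-15), 4422 (HCT116), 5256 (HT-29), 5772 (LoVo), 4041 (LS180), 4800 (SW48), 7578 (SW480), 6804 (SW620), 6156 (SW948) and 4894 (T84) for lines, and 7352 (SW620 against SW480), 2151 (CX-1 against HT-29), 6869 (HCT-8 against DLD-1) and 3098 (CloneA against DLD-1) for pairs. With treat against 1.5-fold, a stricter test, they were 747 (CloneA), 1446 (COLO205), 857 (CX-1), 765 (DLD-1), 1174 (HCT-8), 668 (HCT-15), 1097 (HCT116), 1261 (HT-29), 1356 (LoVo), 874 (LS180), 1012 (SW48), 1706 (SW620) and 1083 (T84) for lines, and 2590 (SW620 against SW480), 393 (CX-1 against HT-29), 178 (HCT-15 against DLD-1), 2247 (HCT-8 against DLD-1) and 494 (CloneA against DLD-1) for pairs.

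With only probes above background on all 32 arrays, which tests fewer probes, the probes differing across the 16 cell lines numbered 7304, 12 list tests over lines and 3 over pairs were called, and the called probes were 446 (CloneA), 784 (COLO205), 1035 (COLO320), 432 (CX-1), 578 (DLD-1), 684 (HCT-8), 336 (HCT-15), 553 (HCT116), 655 (HT-29), 823 (LoVo), 418 (LS180), 622 (SW48), 1095 (SW480), 958 (SW620), 1184 (SW948) and 617 (T84) for lines, and 2104 (SW620 against SW480), 484 (CX-1 against HT-29), 132 (HCT-15 against DLD-1), 2010 (HCT-8 against DLD-1) and 752 (CloneA against DLD-1) for pairs. Under that filter the cancer-testis list in CX-1 reversed in camera direction (median -0.85), as did the xenobiotic list in SW48 (0.41), over fewer members.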

Other observations

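The tests in this part were set before their results were seen, except that the restriction to lost genes called lower, and the rule for leaving the raised genes undecided, were set after.

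By the quality flags, 171 genes were above background on neither array of 1 line and on all arrays of the other lines, and 167 of them were also called lower in that line. Of the 167, 86 were in COLO320, 20 in SW620, 12 in LoVo, 9 each in COLO205 and SW48, 7 in HCT116, 5 in HT-29, 4 in CloneA, 3 each in HCT-15 and LS180, 2 each in CX-1, SW480, SW948 and T84, 1 in HCT-8 and 0 in DLD-1. A hypothesis is that segments of DNA were lost, which would silence neighbouring genes together. Among the 171 genes 5 pairs were neighbours, directly adjacent among the measured genes, lost in the same line, against a mean of 0.773 in 10000 random draws from the 6663 genes that could have met the rule, and 8 draws had as many. Among the 167 there were 5 as well, against a mean of 0.765, and 13 draws had as many. The pairs were UBQLN1 and GKAP1 in COLO205, S100A16 and S100A14, SLC12A2 and SLC12A2-DT, and NMRK1 and OSTF1 in COLO320, and ZNF701 and ZNF137P in SW48. The count of 5 is consistent with lost segments for a few genes, but neighbours that share a promoter or a gene family could be silenced together without any loss of DNA, and DNA was not measured.

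A like hypothesis, that gained segments raised neighbouring genes together, was tested on 61 genes at least 8-fold higher in 1 line than in the next. Among them 0 directly adjacent pairs were found, against a mean of 0.0402 in 10000 draws, so the test could not decide. KLK5 and KLK7, of 1 gene family and both raised in SW48, had 1 measured gene between them and were not counted.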
